A study of Mus musculus with 72 samples.

How the data were processed

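Total RNA of kidney cortex and kidney medulla from Balb/c mice was extracted with the RNeasy Lipid Tissue kit, checked on a Bioanalyzer, labelled with biotin and hybridized to Illumina MouseRef-8 arrays, per the labels. The deposited values of the 72 arrays are intensity values on a linear scale. The authors quantile-normalized these intensities over all 72 arrays, as the values show: the sorted columns differ by at most 1.26 intensity units. The smallest value is 95.3; whether a background was subtracted is not stated, and neither the labels nor the table name the software. A second deposited table holds values from before normalization in 144 columns, 72 of signal and 72 of detection p-values. Its columns are named per the file headers by tissue and a number, 36 numbers per tissue and the same 36 in both tissues. No label carries these numbers, so none of the 144 columns could be given a sample, and the table was not used.

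The deposited intensities were log2-transformed without an offset. Of 25697 probes, 23978 matched 1 gene symbol, 0 matched several and 1719 had none and were left out. These symbols covered 16593 genes. A probe was kept where its intensity was 150 or more on all 3 arrays of at least 1 group of the tissue. This floor replaces a planned filter on detection p-values, which could not be assigned to samples; it was chosen after seeing the overall distribution of intensities, and no other floor was tried. Each gene was read from its probe with the highest mean over the 72 arrays, which left 8671 genes in the cortex, 8678 in the medulla and 9002 in the joint fit. The number of arrays limits the precision.

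Samples were grouped by tissue, dose and time as their labels give them. Group means were fitted with limma 3.58.1 (lmFit, and eBayes with a trend) in R 4.3.3, over the 36 arrays of a tissue or all 72 arrays for comparisons of tissues. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. There were 34 comparisons: each of 3 doses against the control of the same time and averaged over the 3 times, 10 against 0.3 Gy, dose by time (moderated F), controls at 4.5 against 1.5 months, the difference between the tissues' responses, and control medulla against cortex. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, in lists with at least 5 measured members, adjusted over lists and the 3 doses within a tissue. The list tests of the other comparisons were adjusted within each comparison. The 34 lists cover pathways of radiation response, inflammation and metabolism and markers of kidney and other cell types. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.

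The comparisons, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule named, for each averaged comparison, the 10 largest rises and falls among genes past the threshold with the same sign at all 3 times, or the 5 smallest p where fewer than 5 passed; the 2 largest rises and falls at a single time; list members past the threshold; the 5 smallest p of the tests of differences; and the 5 largest rises and falls for the controls. The text names fewer where the rule gives many. Genes named over 35 cortex arrays follow the same rules, applied after the array that stood apart had been seen. In the interaction test genes are ranked by the F test. Counts of arrays above or below control use the control mean of the same time without that array.

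The alternatives run were array weights, cyclic loess, normexp background correction with an offset of 50, no filter, the mean of all probes of a gene, only the arrays of the compared groups, the replicate number as a block, each array of the compared groups left out in turn, and an estimated correlation. Cyclic loess and normexp were applied to the deposited normalized intensities, and this form, like leaving out the array that stood apart, was chosen after seeing the data. Background correction of the signals from before normalization (neqc), the detection filter, values without background correction, loess in place of quantile normalization and the array chip as a block need the unassigned columns or chip names and were not run; the series' processed values, planned as an alternative, became the main ones.

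The procedure was tested on simulated data, with 50 genes changed at each size. In the cortex the averaged comparison recovered 64, 88, 98 and 100 percent of changes of 0.3, 0.5, 0.75 and 1 log2 units, and a comparison at 1 time 12, 64, 92 and 98 percent; in the medulla these were 66, 86, 100 and 100 percent, and 32, 54, 92 and 98 percent. False calls were 15 of 190, 6 of 139, 10 of 186 and 8 of 146. The simulated spread of the cortex came from a fit without the array that stood apart. That fit had a median SE of 0.0733 for 10 Gy averaged over time, against 0.0935 over all arrays. The main cortex tests keep the array, so these shares likely overstate what they recover. All sizes were changed together, and so many changed genes ease the adjusted threshold in both tissues. Correlations expected from shared controls were simulated with 50 draws, each gene drawn independently. No 2 arrays had identical values; 0 identical pairs were found, and the closest replicate pairs of a group differed by 0.192 to 0.329 log2 units (root mean square).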

Results

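Total RNA from kidney cortex and kidney medulla of Balb/c mice was measured on 72 Illumina MouseRef-8 expression arrays. The mice had received 177Lu, a beta-emitting radionuclide, or served as controls. The exposed groups carried absorbed kidney doses of 0.3, 3 or 10 Gy, and tissue was taken at 1.5, 3 or 4.5 months. Each of the 24 groups (2 tissues, control and 3 doses, 3 times) held 3 arrays. The deposited intensities began at 95.3, and the medians of the arrays lay between 143.4 and 143.9. The number of arrays limits the precision of every value below. The labels do not say whether the 3 samples of a group came from separate animals, so the p-values measure only the spread between these samples.

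1 array stood apart from all others. Replicate 3 of the cortex controls at 1.5 months had a mean Pearson r, across genes, of 0.638 with the other cortex arrays, whereas the lowest mean r of any other cortex array was 0.963. Genes are not independent replicates, so this r is descriptive. On this array the macrophage markers lay a median of 3.11 log2 units, and the erythroid and blood markers 4.87, above the other cortex arrays, and the proximal tubule markers lay at -4.14 and the thick ascending limb markers at -4.18. Slpi, a secreted protease inhibitor of leukocytes and mucosa, was higher on it than the mean of the other 2 controls at 1.5 months by 7.25 log2 units, and Slc34a1, the phosphate transporter of the proximal tubule, was at -7.22 from that mean. The array was kept, and where a count of called genes in the cortex moves without it, the count over the other 35 arrays is given. Leaving it out was chosen after its values were seen.

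**Figure D1:**
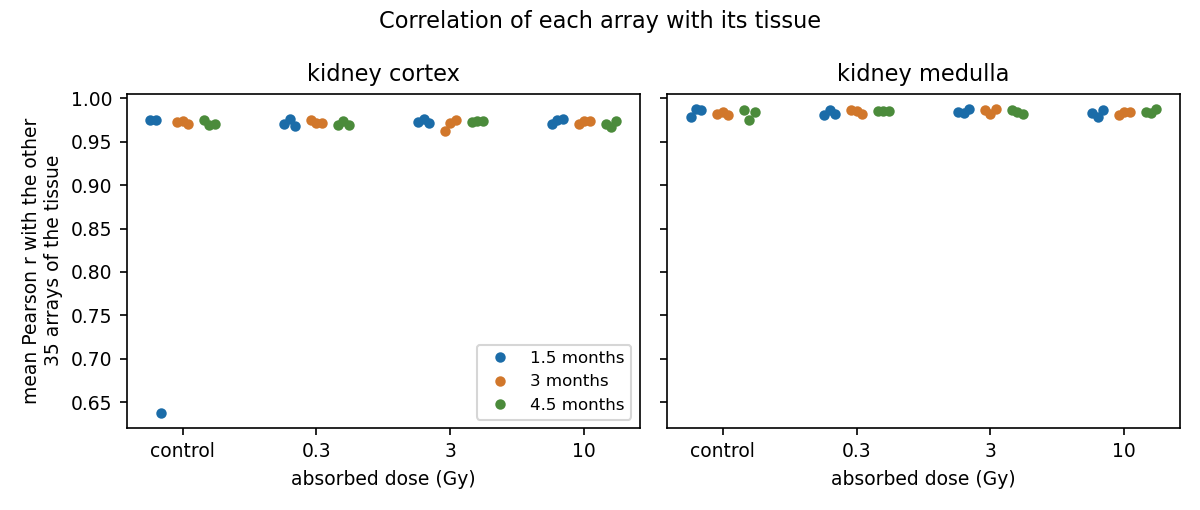
Mean Pearson r, across genes, of each array with the other 35 arrays of its tissue, against absorbed dose in Gy, 1 point per array, colored by time. Replicate 3 of the cortex controls at 1.5 months lies at 0.638, and every other cortex array is at 0.963 or above.

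The first question was which genes differ from control in the cortex at each absorbed dose, averaged over the 3 times. At 0.3 Gy, 2 of 8671 genes passed in limma, both higher. Rcan1, an inhibitor of the phosphatase calcineurin, rose by 0.60 ± 0.11 log2 units (SE; adjusted p = 0.0333) and lay above its control mean on 8 of 9 arrays. Ier5l, a relative of the immediate early gene Ier5, rose by 0.51 ± 0.09 (adjusted p = 0.0333) on 7 of 9 arrays. Over 25 alternatives, most of which leave out 1 array, the adjusted p ran from 0.00148 to 0.824 for Rcan1, which passed in 8, and from 0.00705 to 0.824 for Ier5l, which passed in 9. The next genes by p did not pass: Insc differed by 0.50 ± 0.10 (adjusted p = 0.0913), Foxi1, a transcription factor of intercalated cells, by 0.39 ± 0.09 (adjusted p = 0.247), and Depp1, a target of FOXO transcription factors, by -1.10 ± 0.25 (adjusted p = 0.247).

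Over 35 cortex arrays, 9 genes passed at 0.3 Gy, 6 higher and 3 lower. Depp1 then fell by 1.35 ± 0.20 (adjusted p = 0.00196; below the control mean on all 9 arrays), and Insc rose by 0.40 ± 0.08 (adjusted p = 0.0217). Dnajb1, a co-chaperone of Hsp70, rose by 0.64 ± 0.11 (adjusted p = 0.0134). Cyp4a14, a fatty acid hydroxylase under PPAR control, read 0.21 ± 0.47 over all arrays and fell by 0.49 ± 0.08 over 35 (adjusted p = 0.00196). The others were Zfp420 and LTO1, which rose, and Reep6, which fell.

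At 3 Gy, 9 genes passed in the cortex, 4 higher and 5 lower. Rcan1 rose by 0.78 ± 0.11 (adjusted p = 0.000796) and Ier5l by 0.53 ± 0.09 (adjusted p = 0.0235), each on 9 of 9 arrays. Diablo, a mitochondrial protein that blocks inhibitors of apoptosis, rose by 0.25 ± 0.05 (adjusted p = 0.045; 9 of 9 arrays). The other higher gene, Nuak2, a kinase related to AMPK, differed by 0.84 ± 0.17 (adjusted p = 0.04), but at 3 months it read 11.83 against 11.93 in the controls, so its direction was not the same at all 3 times. Depp1 fell by 1.23 ± 0.25 (adjusted p = 0.045), with all 9 exposed arrays below the control mean; its mean log2 intensity at 1.5 months was 7.37 ± 0.06 (SD, n = 3) against 8.46 ± 1.28 in the controls. Tgif1, a corepressor of TGF-beta signalling, fell by 0.59 ± 0.12 (adjusted p = 0.045), Ankzf1 fell by 0.40 ± 0.08, Zkscan14 fell by 0.37 ± 0.07 and Prune1 fell by 0.33 ± 0.07 (adjusted p = 0.04 for each of these 3). The calls of Tgif1 and Prune1 rest on 1 probe each: the other probes of Tgif1 differed by -0.04 and 0.01, and those of Prune1 by 0.04, 0.03 and 0.02. Rcan1 passed in 25 of 25 alternatives (adjusted p from 2.04e-05 to 0.0162), Ier5l in 18, Tgif1 in 7 and Depp1 in 3 (adjusted p from 2.04e-05 to 0.39).

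Over 35 cortex arrays, 19 genes passed at 3 Gy, 11 higher and 8 lower, and Depp1 fell by 1.48 ± 0.20 (adjusted p = 0.000254). The chaperone genes Dnajb1 and Chordc1, the latter a co-chaperone of Hsp90, then rose by 0.59 ± 0.11 (adjusted p = 0.0173) and 0.38 ± 0.07 (adjusted p = 0.0137). Igfbp1, an insulin-like growth factor binding protein, fell by 0.67 ± 0.12 (adjusted p = 0.0137).

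At 10 Gy, 1 gene passed in the cortex. Ltc4s, which makes leukotriene C4, rose by 0.67 ± 0.09 (adjusted p = 0.000833) on 9 of 9 arrays, from mean log2 intensities of 7.78 ± 0.16, 7.96 ± 0.16 and 7.94 ± 0.13 (SD, n = 3) in the controls at 1.5, 3 and 4.5 months to 8.63 ± 0.31, 8.44 ± 0.09 and 8.62 ± 0.07. Cdkn1a, the cell cycle inhibitor p21 and a target of p53, differed by 0.81 ± 0.17 and did not pass (adjusted p = 0.277), although 9 of 9 arrays lay above the control mean. Its 10 Gy means were 8.57 ± 0.08, 8.37 ± 0.13 and 8.76 ± 0.16, and its control means 7.59 ± 0.42, 8.0 ± 1.08 and 7.69 ± 0.24. Without the array that stood apart, 2 genes passed: Ltc4s, and Cdkn1a, which rose by 0.89 ± 0.17 (adjusted p = 0.0496). The widest control group of Cdkn1a, at 3 months, holds 1 high array: without that replicate 3, Cdkn1a rose by 1.02 (adjusted p = 5.86e-06). That array was singled out by its Cdkn1a level, so leaving it out must raise the difference, and this p is not support. Over 25 alternatives Cdkn1a passed in 4 (adjusted p from 5.86e-06 to 0.91) and Ltc4s in 25 (adjusted p from 0.000292 to 0.0109). Ttc30a1, Scnm1 and Slc19a2, a thiamine transporter, had the next smallest p and did not pass (adjusted p = 0.764 each).

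**Figure D2:**
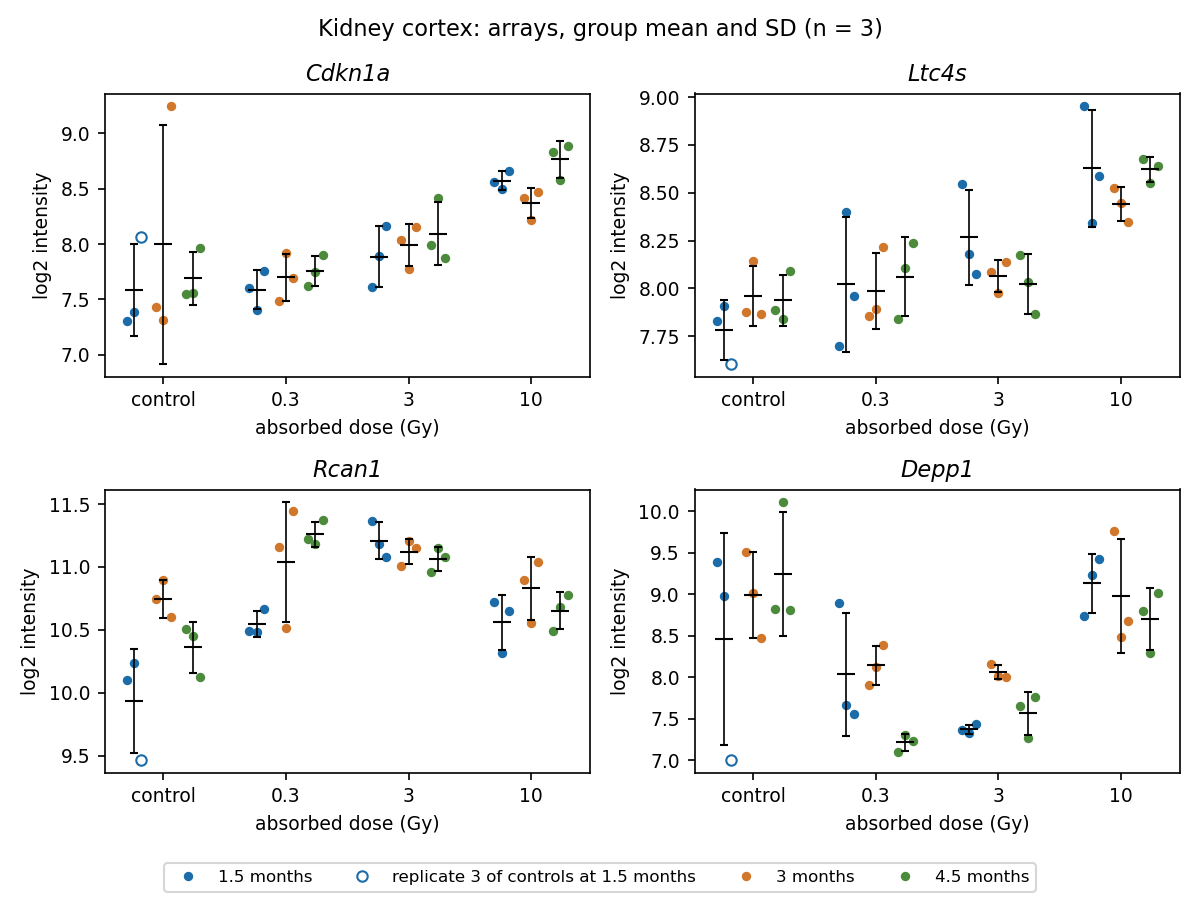
Log2 intensity of Cdkn1a, Ltc4s, Rcan1 and Depp1 in the cortex against absorbed dose in Gy, 1 point per array, with group mean and SD (n = 3), colored by time and with the open circle marking replicate 3 of the controls at 1.5 months. Ltc4s was highest at 10 Gy, with a mean of 8.63 at 1.5 months, whereas the highest group mean of Rcan1, 11.26, and the lowest of Depp1, 7.21, were at 0.3 Gy and 4.5 months.

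Among the p53 target genes, 22 were measured in the cortex, and at 10 Gy 16 lay above 0 and 6 below, with a median of 0.10. The list shifted higher by camera (adjusted p = 0.00644), a call lost with the other estimate (adjusted p = 0.105 with an estimated correlation); 0 members passed over all genes in limma, and 2, Cdkn1a and Ccng1, passed adjusted over the list alone. Over 35 arrays the list was higher with either estimate (adjusted p = 0.000125, and adjusted p = 0.0215 with an estimated correlation), 1 member passed over all genes, and 6 rose adjusted over the list alone: Cdkn1a, Mdm2, Ccng1, Plk2, Bbc3 and Phlda3. Single members rose at the lower doses too: adjusted over the list alone over 35 arrays, Mdm2 and Pmaip1 rose by 0.24 and 0.33 at 0.3 Gy and by 0.23 and 0.36 at 3 Gy. At 10 Gy Mdm2 rose by 0.22, and Pmaip1 read 0.08 and did not pass (adjusted p = 0.556, over the list alone). Over all arrays Ddb2 fell by 0.25 at 3 Gy adjusted over the list alone (adjusted p = 0.0275). The list was not called at 0.3 Gy (adjusted p = 0.575) or 3 Gy (adjusted p = 0.924) over all 36 arrays.

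**Figure D3:**
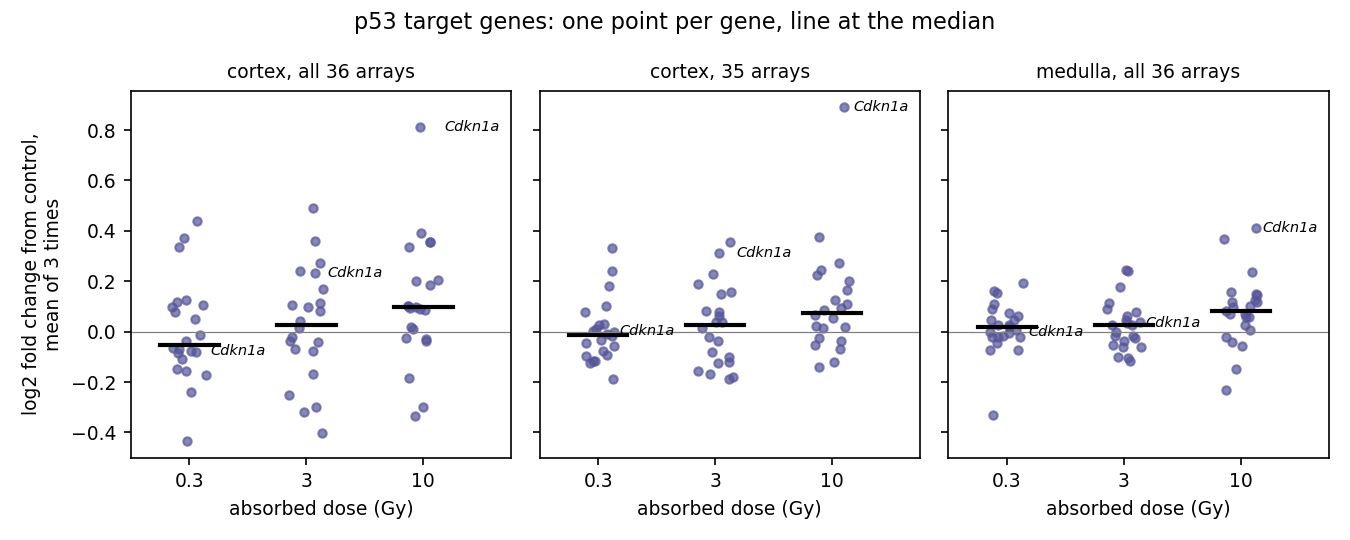
Log2 fold change from control, mean of 3 times, of each measured p53 target gene against absorbed dose in Gy, in the cortex over 36 and 35 arrays and in the medulla, 1 point per gene and a line at the median. At 10 Gy the medians are 0.10, 0.08 and 0.08.

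Over all 36 cortex arrays, 36 of 99 list tests were called by camera and 0 with an estimated correlation (smallest adjusted p = 0.105 with an estimated correlation). The MHC and antigen presentation genes were lower at 0.3 Gy, with all 19 members below 0 and a median of -0.60 (adjusted p = 1.29e-08; adjusted p = 0.747 with an estimated correlation), and the proximal tubule markers were higher, with a median of 0.53 (adjusted p = 0.00556; adjusted p = 0.747 with an estimated correlation). Both move with the array that stood apart, on which the MHC genes lay 2.66 log2 units higher than on the other cortex arrays. Over 35 arrays 11 tests were called, 1 of them with an estimated correlation. The fatty acid oxidation and PPAR genes were then lower at 0.3 Gy, with 20 of 25 members below 0 and a median of -0.14 (adjusted p = 8.01e-08; adjusted p = 0.0669 with an estimated correlation); 1 member passed over all genes and 6 fell adjusted over the list alone. The adipocyte markers were lower at 0.3 Gy as well, with all 12 members below 0 and a median of -0.33 (adjusted p = 0.00973; adjusted p = 0.735 with an estimated correlation); 0 members passed in limma over all genes, and 0 adjusted over the list alone. The fatty acid oxidation and PPAR list was lower at 3 Gy, with a median of -0.10 (adjusted p = 0.000324; adjusted p = 0.377 with an estimated correlation). The extracellular matrix and fibrosis genes were higher at 3 Gy, with 21 of 25 members above 0 (adjusted p = 0.00214; adjusted p = 0.735 with an estimated correlation). So were the adrenal, pancreas, muscle and liver markers, with all 5 members above 0 and a median of 0.29 (adjusted p = 0.0304; adjusted p = 0.191 with an estimated correlation), of which Cela1 and Apoa2 rose adjusted over the list alone. The thick ascending limb markers were lower at 3 Gy, with a median of -0.12 (adjusted p = 0.0304; adjusted p = 0.735 with an estimated correlation). At 10 Gy, beside the p53 targets, the cholesterol synthesis genes were lower, with 11 of 14 members below 0 (adjusted p = 0.00521; adjusted p = 0.522 with an estimated correlation). The tubular injury genes were higher (median 0.05, adjusted p = 0.0475; adjusted p = 0.735 with an estimated correlation). The proliferation genes were higher too (median 0.05, adjusted p = 0.0232; adjusted p = 0.421 with an estimated correlation), whereas over all 36 arrays they were lower (median -0.23, adjusted p = 0.0228; adjusted p = 0.747 with an estimated correlation). The MHC genes were lower at 0.3 Gy here too, with a median of -0.23 (adjusted p = 0.000499; adjusted p = 0.735 with an estimated correlation).

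At single times, 3 arrays were set against 3 in the cortex. At 1.5 months and 3 Gy, 3 genes passed: Ier3, an immediate early gene of the stress response, rose by 1.96 ± 0.35 (adjusted p = 0.0179), Nuak2 by 1.66 ± 0.29 (adjusted p = 0.0158) and Rcan1 by 1.27 ± 0.19 (adjusted p = 0.00248), each on 3 of 3 arrays. Without the array that stood apart, Rcan1 alone passed, at 1.04 ± 0.18 (adjusted p = 0.0285), with Ier3 at 1.37 ± 0.29 (adjusted p = 0.125) and Nuak2 at 1.61 ± 0.31 (adjusted p = 0.0727). At 4.5 months and 3 Gy 1 gene passed over all arrays: Hamp, which encodes the iron regulator hepcidin, rose on 3 of 3 arrays to 7.96 ± 0.50 (SD, n = 3; adjusted p = 0.000231), whereas all 3 controls lay under the intensity floor of 150, which makes it at least 1.66-fold higher. Hamp did not lie above that floor on all arrays of any other cortex group. Over 35 arrays 3 genes passed there: Hamp (adjusted p = 0.000146) and the apolipoprotein genes Apoa2 and Apof, which, like Hamp, are expressed mainly in liver. Apoa2 rose by 1.85 ± 0.34 (adjusted p = 0.0245), with an SD of 1.08 over the 3 exposed arrays, and Apof rose to 7.52 ± 0.24 (SD, n = 3; adjusted p = 0.0245) from controls that all lay under the floor.

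In the other 7 comparisons of a dose with control at 1 time in the cortex, limma called 0 genes. The counts at an unadjusted p under 0.05 were 2164, 226 and 368 for 0.3 Gy at 1.5, 3 and 4.5 months, 521 for 3 Gy at 3 months, and 2218, 128 and 142 for 10 Gy. Over 35 arrays, 0.3 Gy at 1.5 months again had 0 genes by limma, with 271 at an unadjusted p under 0.05; this number was 511 and 798 for 0.3 Gy at 3 and 4.5 months and 1079 for 3 Gy at 3 months. Then 0.3 Gy at 3 months had 2 genes: Cyp4a14 fell by 0.76 ± 0.13 (adjusted p = 0.0149) and Chordc1 rose by 0.66 ± 0.12 (adjusted p = 0.0218). At 4.5 months 0.3 Gy had 16 genes: Depp1 fell at least 3.97-fold (adjusted p = 0.0138), to a mean under the floor, Slc22a13, a urate and organic anion transporter, fell by 2.24 ± 0.49 (adjusted p = 0.0482), and Mdm2, the ubiquitin ligase of p53, rose by 0.53 ± 0.10 (adjusted p = 0.0157). Then 3 Gy at 3 months had 4 genes, among them Noct, a rhythmically expressed phosphatase, which fell by 1.62 ± 0.31 (adjusted p = 0.0268), and Chordc1, which rose by 0.73 ± 0.12 (adjusted p = 0.00807). The 10 Gy groups had 0 genes by limma at each time over 35 arrays too, with 287, 291 and 377 at an unadjusted p under 0.05.

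Whether the highest dose differed from the lowest was tested directly. In the cortex Ltc4s was higher at 10 than at 0.3 Gy by 0.54 ± 0.09 (adjusted p = 0.0311; 9 of 9 arrays), and it was the 1 gene that passed. That call held in 8 of 25 alternatives (adjusted p from 0.00246 to 0.144). Cdkn1a differed by 0.89 ± 0.17 (adjusted p = 0.0824) and Depp1 by 1.14 ± 0.25 (adjusted p = 0.361). Over 35 arrays 4 genes passed: Ltc4s (adjusted p = 0.0109), Cdkn1a (adjusted p = 0.0191) and Depp1 (adjusted p = 0.0109) were higher at 10 Gy, and Zfp46 was lower, at -0.34 ± 0.07 (adjusted p = 0.0347). The p53 target genes were higher at 10 than at 0.3 Gy, with a median of 0.05 (adjusted p = 1e-05; adjusted p = 0.000398 with an estimated correlation); 0 members passed over all genes in limma, and adjusted over the list alone 3 were higher and 1 lower. The test of whether the difference from control changes with time called 0 cortex genes in limma, with 238 at an unadjusted p under 0.05. Without the array that stood apart Hamp and Chordc1 passed it (adjusted p = 0.0283 each), and 480 genes had an unadjusted p under 0.05.

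The same questions were asked of the medulla, where every array had a mean r of 0.975 or more with the others. At 0.3 Gy 2 of 8678 genes passed. Dnajb1 rose by 0.47 ± 0.08 (adjusted p = 0.0208) on 8 of 9 arrays, and Tnfrsf21, a death receptor of the TNF receptor family, fell by 0.49 ± 0.09 (adjusted p = 0.0208) on 9 of 9 arrays; a further Tnfrsf21 probe read -0.47. Chordc1 differed by 0.33 ± 0.07, Tmod4 by 0.25 ± 0.05 and Tmem185b by 0.24 ± 0.05, and these did not pass (adjusted p = 0.0518 each). Over 25 alternatives Dnajb1 passed in 20 (adjusted p from 0.00176 to 0.15) and Tnfrsf21 in 19 (adjusted p from 0.0061 to 0.31).

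At 3 Gy 6 medulla genes passed, 4 higher and 2 lower. The chaperone genes Dnajb1 and Chordc1 rose by 0.47 ± 0.08 (adjusted p = 0.0112; 9 of 9 arrays) and 0.39 ± 0.07 (adjusted p = 0.0116; 8 of 9 arrays). Depp1 fell by 0.72 ± 0.12 (adjusted p = 0.00771) on 9 of 9 arrays. Lhfpl2 rose by 0.43 ± 0.08 (adjusted p = 0.0132) and Rbm15, an RNA-binding protein, by 0.24 ± 0.05 (adjusted p = 0.0395). Cxcl13, a chemokine that attracts B cells, fell by 0.40 ± 0.08 (adjusted p = 0.0346) on 8 of 9 arrays. Over 25 alternatives Depp1 and Dnajb1 passed in 25, Chordc1 in 24, Lhfpl2 in 23, Cxcl13 in 12 and Rbm15 in 8.

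At 10 Gy Cxcl13 was the 1 medulla gene that passed; it fell by 0.44 ± 0.08 (adjusted p = 0.0373) on 8 of 9 arrays. Phlda3, a p53 target that restrains AKT signalling, differed by 0.37 ± 0.08 on 9 of 9 arrays and did not pass over all genes (adjusted p = 0.319), nor did Tmod4 at 0.25 ± 0.05 (adjusted p = 0.141), Tmem185b at 0.19 ± 0.05 (adjusted p = 0.518) or Slc46a3 at -0.33 ± 0.08 (adjusted p = 0.354). Cxcl13 passed in 7 of 25 alternatives (adjusted p from 0.00419 to 0.608), so its call at 10 Gy depends on single arrays.

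**Figure D4:**
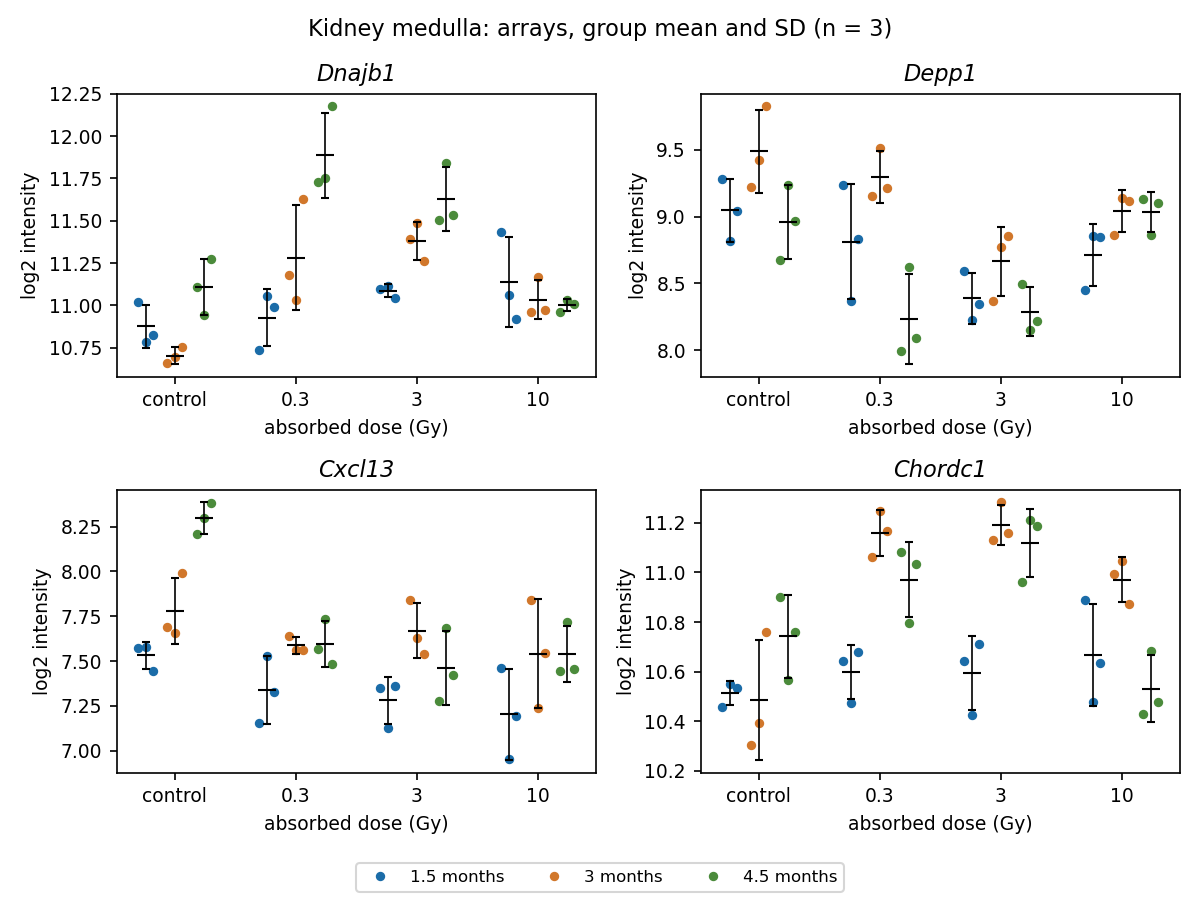
Log2 intensity of Dnajb1, Depp1, Cxcl13 and Chordc1 in the medulla against absorbed dose in Gy, 1 point per array, with group mean and SD (n = 3), colored by time. Cxcl13 at 4.5 months was 8.30 in the controls and 7.60, 7.46 and 7.54 at 0.3, 3 and 10 Gy.

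In the medulla, 10 of 96 list tests were called by camera, and 0 with an estimated correlation. The p53 target genes at 10 Gy had 18 of 23 members above 0 and a median of 0.08 (adjusted p = 0.00191; adjusted p = 0.226 with an estimated correlation); 0 members passed over all genes in limma and 1, Phlda3, rose adjusted over the list alone. The interferon-stimulated genes were higher at 10 Gy, with 24 of 25 members above 0 and a median of 0.14 (adjusted p = 5.51e-05; adjusted p = 0.85 with an estimated correlation). The tubular injury genes were higher at 10 Gy (median 0.07, adjusted p = 0.00881; adjusted p = 0.85 with an estimated correlation), and the thick ascending limb markers were lower (median -0.10, adjusted p = 0.00823; adjusted p = 0.226 with an estimated correlation). The NRF2 antioxidant genes were lower at 0.3 Gy (median -0.10, adjusted p = 0.00191; adjusted p = 0.226 with an estimated correlation) and at 10 Gy (median -0.08, adjusted p = 0.00307; adjusted p = 0.228 with an estimated correlation). The MHC and antigen presentation genes were lower at 0.3 Gy, with 17 of 19 members below 0 and a median of -0.19 (adjusted p = 0.00018; adjusted p = 0.929 with an estimated correlation). The fatty acid oxidation and PPAR genes were lower at 0.3 Gy (median -0.07, adjusted p = 0.00683; adjusted p = 0.636 with an estimated correlation) and at 10 Gy (median -0.05, adjusted p = 0.0336; adjusted p = 0.85 with an estimated correlation). The extracellular matrix and fibrosis genes were higher at 3 Gy, with 21 of 26 members above 0 (adjusted p = 0.0336; adjusted p = 0.975 with an estimated correlation).

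At single times in the medulla, Cxcl13 at 4.5 months was lower than in the controls at every dose, by 0.70 ± 0.14 at 0.3 Gy, by 0.83 ± 0.14 at 3 Gy and by 0.76 ± 0.14 at 10 Gy (adjusted p = 0.0377, 0.00931 and 0.0448), each on 3 of 3 arrays. The 3 comparisons share 1 control group, in which Cxcl13 was 8.30 ± 0.09 (SD, n = 3). That group was itself higher than the controls at 1.5 months by 0.76 ± 0.14, about the size of these differences. A high level in this 1 control group therefore cannot be told apart from a fall after exposure. The averaged falls of Cxcl13 at 3 and 10 Gy include the same group. At 3 months Chordc1 rose by 0.68 ± 0.12 at 0.3 Gy (adjusted p = 0.0323) and by 0.71 ± 0.12 at 3 Gy (adjusted p = 0.0154). Fkbp5, a co-chaperone induced by glucocorticoids, fell by 1.39 ± 0.27 at 0.3 Gy (adjusted p = 0.0458), and Noct fell by 1.10 ± 0.21 at 3 Gy (adjusted p = 0.0454). At 4.5 months and 0.3 Gy, Dnajb1 rose by 0.78 ± 0.14 (adjusted p = 0.0287) and Slc25a25, a mitochondrial carrier of adenine nucleotides, by 1.10 ± 0.22 (adjusted p = 0.0377). In all, 0.3 Gy had 5 genes at 3 months and 6 at 4.5 months, 3 Gy had 4 and 1, and 10 Gy had 1 at 4.5 months. With each array of the compared groups left out in turn these 5 counts ranged from 0 to 20, 0 to 2, 0 to 12, 0 to 1 and 0 to 5. In the other 4 comparisons limma called 0 genes, with 420 at 0.3, 412 at 3 and 327 at 10 Gy at 1.5 months and 552 at 10 Gy at 3 months at an unadjusted p under 0.05.

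Between 10 and 0.3 Gy in the medulla limma called 0 genes, with 613 at an unadjusted p under 0.05; Atxn1 (-0.40 ± 0.08, adjusted p = 0.0989) and Nsd1 (-0.40 ± 0.08, adjusted p = 0.105) had the smallest p. The interferon-stimulated genes were higher at 10 than at 0.3 Gy, with 24 of 25 members above 0 and a median of 0.18 (adjusted p = 1.93e-09; adjusted p = 0.476 with an estimated correlation), and so were the p53 target genes (median 0.04, adjusted p = 0.0402; adjusted p = 0.485 with an estimated correlation). The test of dose by time called 0 medulla genes in limma, with 506 at an unadjusted p under 0.05; Srf and Per2, a clock gene, were among the 5 smallest p (adjusted p = 0.353 each).

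Whether cortex and medulla respond differently was tested as the difference of their time-averaged changes. No single gene passed: limma called 0 genes at 0.3, 3 and 10 Gy, with 615, 328 and 517 at an unadjusted p under 0.05 (518, 231 and 362 without the array that stood apart). The smallest p belonged to Chac1, a glutathione-degrading enzyme, at 0.3 Gy (0.55 ± 0.14, adjusted p = 0.713), Hamp at 3 Gy (-0.36 ± 0.10, adjusted p = 0.791) and Piga at 10 Gy (0.40 ± 0.10, adjusted p = 0.714). Over 35 cortex arrays, the 19 genes called in the cortex at 3 Gy all had the same sign in the medulla, and so did the 9 genes called at 0.3 Gy and the 2 at 10 Gy. The tissues may share animals, controls included, as 21 of 36 cortex arrays were closest to the medulla array of their own number, against 12 by chance. The shared sign is therefore not independent evidence, and the share of all genes with the same sign was not counted. Across 8347 genes, which are not independent replicates, the changes in cortex and medulla then correlated with r of 0.27 at 0.3 Gy, 0.57 at 3 Gy and 0.05 at 10 Gy. Over all arrays r was 0.14, 0.39 and -0.15 at these doses, so it depends on the array that stood apart.

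Within a tissue the doses share their controls, which alone correlates their changes. The simulation drew each gene independently and does not cover variation that genes share. A gap from the simulated r therefore does not by itself show a dose effect. In the cortex over 35 arrays the changes at 0.3 and 3 Gy correlated with r = 0.58 across genes, against 0.54 simulated for shared controls alone, and 4 genes were called at both doses (Dnajb1, Rcan1, Depp1 and Ier5l). The changes at 3 and 10 Gy correlated with r = 0.08 and those at 0.3 and 10 Gy with r = 0.49, against 0.54 simulated for each. With different controls for each dose, r varied widely with the controls chosen. It ran from -0.0956 to 0.466 for 0.3 and 3 Gy, from -0.414 to 0.0519 for 3 and 10 Gy and from -0.0682 to 0.286 for 0.3 and 10 Gy. Over all 36 arrays each dose is set against the array that stood apart. There r was 0.84 for 0.3 and 3 Gy, 0.67 for 3 and 10 Gy and 0.83 for 0.3 and 10 Gy, against 0.50 simulated for each. In this fit 2 genes were called at both 0.3 and 3 Gy (Rcan1 and Ier5l). In the medulla r was 0.59 for 0.3 and 3 Gy, 0.40 for 3 and 10 Gy and 0.46 for 0.3 and 10 Gy, against 0.50 simulated for each. Dnajb1 was called there at both 0.3 and 3 Gy and Cxcl13 at both 3 and 10 Gy.

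The unexposed tissues were compared as a background. Medulla differed from cortex in 2498 of 9002 genes, 1345 higher and 1153 lower (3367 over 71 arrays). Npy rose by 3.88 ± 0.23 (adjusted p = 1.75e-19), Slc14a2, the urea transporter of the inner medulla, by 3.86 ± 0.23 (adjusted p = 2e-19) and Aqp4, a water channel of principal cells, by 2.86 ± 0.22 (adjusted p = 1.78e-15), each on 9 of 9 arrays. Adipoq, an adipocyte hormone, was lower by -1.45 ± 0.51 (adjusted p = 0.0274) and Clu, the secreted chaperone clusterin, by -1.41 ± 0.15 (adjusted p = 9.76e-11). Of the thin limb and inner medulla markers, 11 of 12 were higher (median 1.03, adjusted p = 1.53e-14; adjusted p = 2.79e-05 with an estimated correlation), 11 also when adjusted over the list alone. Of the distal convoluted tubule markers 6 of 10 were lower, 8 when adjusted over the list alone (median -0.82, adjusted p = 0.000513; adjusted p = 0.428 with an estimated correlation), and of the podocyte and glomerular markers 5 were lower, 6 when adjusted over the list alone, among them Wt1 at -1.05 ± 0.11 (list adjusted p = 0.0194; adjusted p = 0.379 with an estimated correlation).

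In the control medulla 3 genes differed between 1.5 and 4.5 months. Cxcl13 rose by 0.76 ± 0.14, from 7.53 ± 0.08 to 8.30 ± 0.09 (SD, n = 3), Gpr65, an acid-sensing receptor of leukocytes, rose by 0.69 ± 0.13, and Serpina6, the corticosteroid-binding globulin, fell by 1.91 ± 0.36 (adjusted p = 0.0334 each, 3 of 3 arrays each). Of 13 alternatives, Cxcl13 passed in 6, Gpr65 in 5 and Serpina6 in 6. The macrophage and dendritic cell markers rose together, with all 14 members above 0 and a median of 0.73 (adjusted p = 1.89e-14; adjusted p = 0.0392 with an estimated correlation), and 12 members rose adjusted over the list alone while 0 passed over all genes in limma. In the control cortex limma called 0 genes between these times, with 2044 at an unadjusted p under 0.05. Leaving out the array that stood apart leaves replicates 1 and 2 of the controls at 1.5 months. Without the array that stood apart 803 had such a p and 1 passed: Adgre1, the macrophage antigen F4/80, which read -0.30 ± 0.49 over all arrays, rose by 0.93 ± 0.16 (adjusted p = 0.0246), and the macrophage and dendritic cell markers had a median of 0.55 in place of -0.38 (adjusted p = 1.36e-15; adjusted p = 0.0197 with an estimated correlation).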

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

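The tests on the array that stood apart, on the genes of 0.3 and 3 Gy and on the dose relation of the p53 targets, the adjusted p of the p53 targets with 1 array left out, and all counts of other splits, were chosen only after the result was seen. The unadjusted test of the p53 targets with 1 array left out at a time was fixed before its result was seen.

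The endothelial markers responded to 3 Gy differently in the 2 tissues by a direct test of the difference, with a median of -0.111 for medulla minus cortex without the array that stood apart (adjusted p = 0.0054; adjusted p = 0.812 with an estimated correlation) and -0.109 with it (adjusted p = 0.0171; adjusted p = 0.569 with an estimated correlation). Of 34 lists, 13, 16 and 14 were called in this way at 0.3, 3 and 10 Gy over all arrays, and 0, 1 and 0 without that array; 0 were called with an estimated correlation.

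Replicate 3 of the cortex controls at 1.5 months was low in tubule transcripts and high in those of blood and immune cells. Umod, Slc34a1 and Fxyd2, among its lowest genes, read 7.07, 6.96 and 6.92, under the log2 floor of 7.23. The means of the other 2 controls were 14.19, 14.18 and 14.32. Whether this sample held any kidney cortex is therefore in doubt, and it counts as a control in the results over all 36 cortex arrays. These values do not tell a sample of another tissue from cortex with few tubule transcripts. A medulla sample under a cortex label is argued against, since the median of its thick ascending limb markers lay at -4.16 log2 units from the lowest of the 36 medulla arrays. Poor RNA or compressed signals as the whole cause are argued against by 28 genes that were under log2 9 on the other 35 cortex arrays and over log2 12 on this one. Earlier tests had gone the other way and were replaced: its mean r was 0.644 with the cortex controls and 0.663 with the medulla controls, and its slope on the cortex mean was 0.682. RNA of other cells in place of tubule stays open and may account for it: 2 lists of non-tubular cells, macrophage and erythroid, had medians above those of every other cortex array, with Mzb1, Pf4, S100a8, Lyz2 and Alas2 among the genes highest over the mean of the other 2 controls at 1.5 months, and no biological explanation was tested.

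Rcan1, Dnajb1, Chordc1 and Depp1 were called at 0.3 or 3 Gy and not at 10 Gy. Such calls do not by themselves show a difference between the doses. In the direct limma test of 10 against 0.3 Gy, Rcan1, Dnajb1 and Chordc1 passed in neither tissue. Depp1 passed only in the cortex without the array that stood apart (adjusted p = 0.0109, against 0.361 with it). Single genes were not tested between 10 and 3 Gy. An effect that grows with absorbed dose stays open: the 24 genes called in the cortex at 0.3 or 3 Gy, with or without the array that stood apart, moved in the cortex direction in the medulla by a mean of 0.155, 0.204 and 0.0387 at 0.3, 3 and 10 Gy (difference of 10 and 3 Gy -0.165, exact permutation p = 0.00075, 18 arrays), but they were chosen at these doses, and with 21 of 36 cortex arrays closest to the medulla array of their own number, against 12 by chance, the tissues may share animals. A difference in the time of day or feeding at sampling cannot be told apart from dose for these genes, since each dose-and-time group may have been sampled at another hour and the labels give none. Over the 9 groups the clock change in cortex and medulla correlated with Pearson r = 0.63 (permutation p = 0.0637) and Spearman rho = 0.567 (permutation p = 0.12), r was 0.565 without the 2 groups farthest from the median, and the opposite movement of 3 morning and 9 evening clock genes that this explanation needs was not established over 18 groups (r = -0.137, permutation p = 0.586). The clock score itself correlated between the tissues over 12 groups, controls included, with r = 0.87 (permutation p = 0.00028) and 0.547 after centring within time, which goes with sampling at different hours but does not tie it to these genes, and a response to low dose or dose rate stays open as untested.

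The p53 target genes were higher at 10 Gy in both tissues by camera, calls lost over all arrays with the other estimate (adjusted p = 0.105 in the cortex and 0.226 in the medulla with an estimated correlation), so a shift shared by correlated genes stays open. That 1 array carries this is argued against in the medulla, where the largest adjusted p with any 1 array of the compared groups left out was 0.0161, and in the cortex over 35 arrays, where it was 0.014. Over all 36 cortex arrays it stays open: the largest p was 0.0439 unadjusted, under the bound of 0.05 set in advance, but that bound was wrong because the list calls use adjusted p, and this reached 0.0804 without replicate 1 of the controls at 1.5 months, which leaves the array that stood apart as 1 of 2 controls. In the cortex the list was higher at 10 than at 0.3 Gy with a camera p of 6.08e-07 (adjusted p = 0.000398 with an estimated correlation), so an effect that grows with dose may account for the list as a whole. This test leaves out 3 Gy, where the list was not called over all 36 arrays. Members differ: over 35 arrays Cdkn1a read 0.003, 0.31 and 0.89 at 0.3, 3 and 10 Gy, and Mdm2 0.24, 0.23 and 0.22. Pmaip1 read 0.36 at 3 Gy and 0.08 at 10 Gy. In the medulla the camera p of 0.00628 leaves a growth with dose open, as the call is lost with the other estimate (adjusted p = 0.485 with an estimated correlation).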

How the results depend on the processing

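Cyclic loess, normexp and leaving out the array that stood apart, together with the joint use of the latter and the replicate block, were chosen after seeing the data; the other alternatives were planned. Of the comparisons of a named gene with an alternative, 5437 kept their direction and side of the threshold, 460 lost the call, 114 gained one and 5 reversed; of those for the counts, 514 stayed within 1.5 times and 204 moved. Rcan1 at 3 Gy and Ltc4s at 10 Gy in the cortex, and Depp1 and Dnajb1 at 3 Gy in the medulla, passed in all 25 alternatives run for them. The intensities have no measured background, so changes in genes near the floor of 150, such as Hamp and Cxcl13, are limited by signal over background. Replicate numbers do not pair the samples between doses, where the deviations of same-numbered arrays from their group means correlated across genes with a mean r of 0.0412 in the cortex and 0.0475 in the medulla. Between tissues the mean r was 0.177 for the same number (lowest -0.427) and -0.0879 for other numbers. These means are tied to each other, since the deviations within a group cancel out. There 21 of 36 cortex arrays correlated best with their own number, against 12 by chance, a hint, which no label states, that some same-numbered cortex and medulla samples are related. The unassigned columns from before normalization carry the same 36 numbers in both tissues. Those numbers could not be tied to the replicate numbers. Array weights stopped before reaching their convergence tolerance in 2 fits. Where no cause is given below, the cause was not tested.

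With array weights the genes called in the cortex went from 2 to 12 at 0.3 Gy, from 9 to 156 at 3 Gy and from 1 to 2 at 10 Gy averaged over time. At single times they went from 0 to 2 (0.3 Gy, 3 months), 0 to 123 (0.3 Gy, 4.5 months), 3 to 9 (3 Gy, 1.5 months), 0 to 183 (3 Gy, 3 months), 1 to 115 (3 Gy, 4.5 months) and 0 to 2 (10 Gy, 3 months). Further cortex counts went from 1 to 4 (10 against 0.3 Gy), 0 to 16 (dose by time) and 0 to 16 (control age), and the called lists from 36 to 15. In the medulla the averaged counts went from 2 to 90, 6 to 16 and 1 to 0 at 0.3, 3 and 10 Gy. At single times they went from 0 to 412 (0.3 Gy, 1.5 months), 5 to 1 (0.3 Gy, 3 months), 6 to 11 (0.3 Gy, 4.5 months), 4 to 219 (3 Gy, 3 months) and 1 to 8 (10 Gy, 4.5 months). The others went from 0 to 17 (10 against 0.3 Gy), 0 to 11 (dose by time) and 3 to 13 (control age), and control medulla against cortex from 2498 to 3984.

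With only the arrays of the compared groups, which leaves fewer samples to estimate the spread, averaged counts went to 0 and 1 in the cortex at 0.3 and 3 Gy and to 0 in the medulla at 0.3 and 10 Gy. At single times in the cortex they went to 12 (0.3 Gy, 4.5 months), 0 (3 Gy, 1.5 months), 14 (3 Gy, 4.5 months) and 1 (10 Gy, 3 months). In the medulla they went to 0 at 0.3 and 3 Gy at both 3 and 4.5 months, 1 at 10 Gy at 3 months, 0 at 10 Gy at 4.5 months and 0 for control age; control medulla against cortex went to 1246. Without the filter, which tests more genes, counts went to 0 (cortex 0.3 Gy), 2 (cortex 3 Gy), 0 (cortex 10 against 0.3 Gy), 0 (medulla 10 Gy), 0 and 0 (medulla 0.3 Gy at 3 and 4.5 months), 1 (medulla 3 Gy at 3 months) and 0 (medulla 10 Gy at 4.5 months). With the mean of all probes they went to 0, 2 and 2 in the cortex at 0.3, 3 and 10 Gy, 2 for cortex 10 against 0.3 Gy, 8 for medulla 0.3 Gy and 1 for medulla 3 Gy at 3 months.

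With the replicate block counts went to 0 and 1 in the cortex at 0.3 and 3 Gy, 1, 1 and 2 at 3 Gy at 1.5, 3 and 4.5 months, and 0 for 10 against 0.3 Gy. In the medulla they went to 4 at 0.3 Gy, and to 3 and 0 at 3 and 4.5 months. With normexp the medulla went to 0 at 10 Gy, 2 at 0.3 Gy and 4.5 months, 1 at 3 Gy and 3 months and 0 at 10 Gy and 4.5 months. With cyclic loess cortex 3 Gy went to 5, and medulla 0.3 Gy to 14 at 3 months and 0 at 4.5 months. With an estimated correlation the called lists went from 36 to 0 in the cortex and from 10 to 0 in the medulla; without the array that stood apart the cortex lists went to 11, and to 1 with both.

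Signs reversed for 3 genes. Znrd1 in the cortex at 3 Gy read -0.0145 with the mean of probes. Cyp4a14 in the cortex at 0.3 Gy read -0.45 with array weights and -0.49 without the array that stood apart, the lowest of -0.49 to 0.57 with 1 array left out. Adgre1 with control age in the cortex read 0.84 with array weights and 0.93 without that array, the highest of -0.94 to 0.93.

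With each array of the compared groups left out in turn, the averaged counts in the cortex ranged from 0 to 9 at 0.3 Gy, 1 to 187 at 3 Gy and 1 to 2 at 10 Gy. At 1.5 months they ranged from 0 to 2840, 0 to 2741 and 0 to 2820 at the 3 doses, with the maxima when replicate 1 of those controls was left out, so that the array that stood apart made up 1 of 2 controls. Leaving out that replicate 1 also gave the 187. Cortex 3 Gy ranged from 0 to 3 at 3 months and 1 to 4 at 4.5 months, 10 against 0.3 Gy from 0 to 1, dose by time from 0 to 2 and control age from 0 to 2474 (without replicate 2 of the controls at 1.5 months). Leaving out the array that stood apart from cortex comparisons it is not part of, where it only widens the spread, gave 2 and 16 genes at 0.3 Gy at 3 and 4.5 months, 4 and 3 at 3 Gy, and 4 for 10 against 0.3 Gy. In the medulla the averaged counts ranged from 0 to 11, 3 to 6 and 0 to 2. At single times they ranged from 0 to 20 and 0 to 2 (0.3 Gy, 3 and 4.5 months), 0 to 12 and 0 to 1 (3 Gy), and 0 to 2 and 0 to 5 (10 Gy); the 20 was without replicate 2 of the 0.3 Gy group, the 12 without replicate 1 of the controls at 3 months, and the 5 without replicate 2 of the 10 Gy group. The others were 0 to 4 (10 against 0.3 Gy), 0 to 1 (dose by time), 0 to 4 (control age), 0 to 1 (response difference at 0.3 Gy) and 2203 to 3367 (control medulla against cortex).

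Not run were neqc and quantile normalization of the signals from before normalization, the detection filter, loess in their place and the chip as a block, since those columns could not be assigned to samples and no chip is named.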

Other observations

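All counts of other splits were chosen only after the result was seen.

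By camera at the preset correlation, immune gene lists were higher at the later time in unexposed kidney. Of the lists given next, only the complement and acute phase genes passed with an estimated correlation too. In the control medulla from 1.5 to 4.5 months, 12 of 13 complement and acute phase genes lay above 0 (median 0.33, adjusted p = 0.000107; adjusted p = 0.0392 with an estimated correlation), 2 of them past the threshold adjusted over the list alone. The MHC and antigen presentation genes, which display peptides to T cells, had 18 of 19 members above 0 and a median of 0.80 (adjusted p = 1.47e-16; adjusted p = 0.128 with an estimated correlation), 17 of them higher adjusted over the list alone. In the control cortex, over the arrays other than the one that stood apart, the same list had 19 of 19 members above 0 and a median of 1.04 (adjusted p = 4.99e-19; adjusted p = 0.0957 with an estimated correlation), 16 of them higher adjusted over the list alone. The interferon-stimulated genes had a median of 0.52 there (adjusted p = 8.6e-17; adjusted p = 0.0929 with an estimated correlation), 9 of them higher adjusted over the list alone. These cortex results rest on replicates 1 and 2 alone of the controls at 1.5 months.

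Between 10 and 0.3 Gy the MHC and interferon-stimulated genes were higher at 10 Gy, and the complement and acute phase genes were not called (adjusted p = 0.146 in the cortex and 0.247 in the medulla). Against control, the MHC genes were called lower at 0.3 Gy in both tissues. At 10 Gy they were not called over 35 cortex arrays or in the medulla. The interferon-stimulated genes were called higher than control at 10 Gy in the medulla, and not over 35 cortex arrays. The adipocyte markers were called lower than control at 0.3 Gy over 35 cortex arrays. The interferon-stimulated genes had 21 of 25 members above 0 in the cortex and a median of 0.18 (adjusted p = 3.45e-05; adjusted p = 0.864 with an estimated correlation). The MHC genes had 19 of 19 members above 0 in both tissues, with a median of 0.29 in the cortex (adjusted p = 5.96e-06; adjusted p = 0.864 with an estimated correlation) and 0.23 in the medulla (adjusted p = 7.74e-09; adjusted p = 0.485 with an estimated correlation). The adipocyte markers, which include hormones and lipid droplet proteins of fat, had 10 of 12 members above 0 in the cortex and a median of 0.37 (adjusted p = 3.88e-05; adjusted p = 0.715 with an estimated correlation). The cholesterol synthesis genes were lower at 10 than at 0.3 Gy in the cortex, with 12 of 14 members below 0 and a median of -0.13 (adjusted p = 0.0219; adjusted p = 0.806 with an estimated correlation). The tubular injury genes were higher in the medulla, with 17 of 18 members above 0 and a median of 0.09 (adjusted p = 6.59e-05; adjusted p = 0.476 with an estimated correlation), 4 of them adjusted over the list alone. Adjusted over the list alone, 0 members of the MHC, adipocyte and cholesterol lists passed in limma in these comparisons, nor did any interferon-stimulated gene in the cortex.

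Splits of the same arrays were drawn within time and tissue, and each set of 100 includes the real split. In the cortex 2, 1 and 2 of 100 gave at least as many genes as the real one at 0.3, 3 and 10 Gy, itself counted. The real splits had 2, 9 and 1 genes, and the others at most 2, 2 and 1. For 10 against 0.3 Gy it was 2 of 100 (1 gene, at most 1 in the others). At 3 Gy no other split came near the real count, which argues against chance there. The counts of 1 and 2 genes were reached by another split too. Their shares lie under 0.05, but with 100 draws and several comparisons this does not exclude chance. The cortex splits against control also move the array that stood apart. In the medulla it was 2 and 1 of 100 at 0.3 and 3 Gy, the real split counted (2 and 6 genes, at most 3 and 1 in the others). This argues against chance at 3 Gy. At 0.3 Gy another split called more genes than the real one, so chance is not excluded there. For control medulla against cortex, where the splits were drawn within time and across the tissues, it was 1 of 100, the real split alone. It had 2498 genes and the others at most 2220, which argues against chance. The split with 2220 kept 14 of the 18 arrays in their own tissue. Chance is not excluded for the 1 gene of the medulla at 10 Gy, with 6 of 100 splits (at most 1 gene). For the comparisons that called 0 genes all 100 splits gave as many. The highest others were 1 (cortex dose by time), 3 (medulla 10 against 0.3 Gy), 668 (medulla dose by time) and 5, 1 and 7 (response differences at 0.3, 3 and 10 Gy). The cause of the 668 was not tested.

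For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest others in the cortex at 1.5, 3 and 4.5 months were 0, 0 and 0 against 1, 1 and 0 at 0.3 Gy, 3, 0 and 1 against 5, 1 and 0 at 3 Gy, and 0 each against 0 each at 10 Gy. In the medulla they were 0, 5 and 6 against 0, 3 and 2 at 0.3 Gy, 0, 4 and 1 against 0, 0 and 0 at 3 Gy, and 0, 0 and 1 against 1, 229 and 0 at 10 Gy. As many genes as in the real split came from 3 of 10 splits for cortex 3 Gy at 1.5 months, from all 10 where the real count was 0, and from the real split alone in the rest. Control age gave 0 against 190 in the cortex and 3 against 0 in the medulla. The 190 put replicates 1 and 2 of the 1.5-month controls with replicate 1 of the 4.5-month controls, leaving the array that stood apart on the other side. The 229 put replicate 1 of the 3-month controls with replicates 1 and 2 of the 10 Gy group. The cause of these counts was not tested.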
